A study of Mus musculus with 8 samples.

How the data were processed

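Chromatin from skeletal muscle nuclei of wild-type C57/Bl6J mice aged 10 to 12 weeks was immunoprecipitated with antibodies against GR, H3K27ac, Pol2, H3K4me1, CTCF and H3K4me3, with 1 library per antibody and 2 inputs. Libraries were made from 10 ng of DNA with 7 PCR cycles, per the labels' protocols. The 8 samples each carry replicate number 1. Reads of these libraries were not analysed here, and the work rests on the 6 peak lists.

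The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie 1.0.0, MACS2 without a version and the build mm10, and give no role, order, threshold or blacklist for them. The deposited values used here are peak positions in bases, start and end, for all 6 lists, and summit positions for CTCF and H3K4me3. For these 2 lists the authors also deposited an integer score, a linear fold (ratio) of enrichment over the control, and the −log10 p-value and −log10 q-value of each peak. The columns had no header and were told from their values, since the deposited score equalled 10 times the −log10 q-value, truncated to a whole number. The deposited GR, H3K27ac, H3K4me1 and Pol2 lists held positions and a peak name only, so width was used in place of a score, as had been laid down for that case. The library sizes are not given in the sources used here, and the depth is therefore unknown. Intervals cover the counting error of peaks or genes only, taken as independent, and do not cover variation between animals. Peaks can cluster, as with the 28 GR peaks in the region around Fkbp5, so intervals can be too narrow and p values too small. PCR reads without molecular identifiers are not independent molecules, which the intervals do not cover either.

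The gene lists, motifs, tests, most alternative settings and the rule for named genes were fixed before the data were examined. Peaks on the mitochondrial genome (8 GR, 7 H3K4me3, 5 CTCF and 1 Pol2 peaks) were left out of all comparisons. Genes and TSS came from GENCODE annotation of GRCm38, with 21853 protein-coding genes, and sequence from the same build. RefSeq annotation of the same build was used to name what lay under the widest peaks.

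Overlap meant at least 1 shared base. GR peaks were shuffled 1000 times within their chromosomes, away from assembly gaps, and the p values were one-sided and adjusted by Benjamini-Hochberg over the 5 marks. Peaks were put into 5 classes by the histone marks they overlapped: promoter (H3K4me3), enhancer (H3K4me1 and H3K27ac without H3K4me3), H3K4me1 only, H3K27ac only, and none. Shares carry exact Clopper-Pearson 95% intervals, and odds ratios carry conditional exact intervals with two-sided Fisher's exact tests. Odds ratios within strata are Mantel-Haenszel estimates, given without p values. Differences of medians were tested with 100000 permutations. Adjusted p values under 0.05 counted as passing.

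For the 19 gene lists, members were compared with all other protein-coding genes for a GR peak midpoint within 25 kb of a TSS, and for a Pol2, H3K4me3 or H3K27ac peak within 1 kb of a TSS. The lists were GR targets, muscle atrophy and proteolysis, insulin and IGF signalling, fast or common sarcomere, slow sarcomere, neuromuscular junction, muscle transcription factors, glucose and glycogen, fatty acid oxidation and mitochondria, circadian clock, housekeeping, endothelial, fibro-adipogenic and fibroblast, satellite cell, immune, adipocyte, Schwann, liver and neuron. The genes named are 18 genes fixed in advance, the 10 widest GR peaks with the nearest protein-coding TSS, and in each of the first 10 lists up to 3 members with the widest GR peak within 25 kb. A motif among the 14 below and a gene named by this rule are not reported here. Any other gene named was chosen after its values were seen.

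For 14 motifs, given as consensus sequences, windows of 200 bases at GR peak midpoints were scanned on both strands and compared with windows 2 kb to each side that overlapped no GR peak. Among the motifs named below, NF1, CTCF and NRF1 sites could have 1 mismatch. The others, with the GRE, had to match their consensus without a mismatch. The scan left out 20 GR peaks whose windows or control windows met assembly gaps. CTCF windows were centred on summits. GC-matched control windows were drawn once from the flanking windows with replacement, in bins of 2 percentage points. A flanking window could be drawn repeatedly, and the tests counted each draw as independent. Intervals and p values against these controls can therefore be too narrow and too small. Summaries of motifs by class of peak were added after the data were seen.

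The alternatives tried were 50% coverage of a peak, peaks within 1 kb counted as shared, the widest or strongest 50% of peaks, shifts of 10 to 50 kb, the central 200 bases of each peak, strata of width, other TSS windows and annotations, genes with H3K4me3 as the background, and other motif windows and controls. The first 50% of the GR list in its deposited order, the place in that list, and lists without sites shared by CTCF and H3K4me3 were added after seeing the data.

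The overlap, gene-list, peak-number, motif-scan, median and Mantel-Haenszel steps were tested on simulated data; the class comparisons, the GC-matched controls and the shifts of 10 to 50 kb were not. For the overlap test on 23188 simulated peaks, 29.5% were planted on sites and 29.3% were found above chance, and 2.5% of 40 random lists had a permutation p of 0.05 or less. For the gene-list test over 21853 genes, 5.8% of 500 random lists had an unadjusted exact p under 0.05, and 100% of 19 planted lists were recovered. For the peak-number test over the same number of genes, 6.5% of 200 random lists had an unadjusted permutation p under 0.05. The motif scan of 10000 windows found every planted site, with a match in 0.0665% of the 9023 windows without one. A Mantel-Haenszel odds ratio planted at 4 was estimated as 4.27 over 40000 simulated peaks. The permutation test of medians on 600 simulated values gave p = 0.63 with no difference and p = 0.0005 with a planted one. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.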

Results

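The data describe where the glucocorticoid receptor (GR), a hormone-activated transcription factor, sat in the chromatin of mouse skeletal muscle, beside RNA polymerase II (Pol2), the architectural protein CTCF and 3 histone marks. H3K4me3 marks promoters, H3K4me1 marks enhancers and other regulatory DNA, and H3K27ac marks active promoters and enhancers. Chromatin immunoprecipitation with sequencing was done on nuclei from wild-type C57/Bl6J mice aged 10 to 12 weeks. There was 1 library per antibody and there were 2 input libraries, which makes 8 samples. Input 1 belonged with GR, H3K27ac, Pol2 and H3K4me1, and Input 2 with CTCF and H3K4me3. There were no replicates, so every test below counts peaks or genes within single libraries and none measures variation between animals. The read depth of each library is not given in the sources used here.

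The peak lists on the nuclear chromosomes held 23188 GR peaks, 44151 H3K27ac peaks, 75523 H3K4me1 peaks, 19811 H3K4me3 peaks, 20192 Pol2 peaks and 6526 CTCF peaks. The median width was 212 bases for GR, 341 for H3K27ac, 1367 for H3K4me1, 964 for H3K4me3, 212 for Pol2 and 229 for CTCF. GR peaks covered 5.88 Mb of the genome and H3K4me1 peaks covered 182 Mb. The GR list held positions and no score or fold, so width, which ran from 123 to 4129 bases, stood in for the strength of a GR peak. Strength itself was not measured. All positions are on mouse build GRCm38 (mm10).

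Most GR peaks overlapped marks of activity by at least 1 base. H3K27ac peaks overlapped 16072 GR peaks (69.3%, exact 95% interval 68.7 to 69.9%), and H3K4me1 peaks overlapped 15210 (65.6%, 65.0 to 66.2%). H3K4me3 peaks overlapped 12338 GR peaks (53.2%, 52.6 to 53.9%) and Pol2 peaks overlapped 11906 (51.3%, 50.7 to 52.0%). CTCF peaks overlapped 1643 GR peaks (7.09%, 6.76 to 7.42%). When 50% of the GR peak had to be covered, the shares were 48.5% for H3K27ac, 63.2% for H3K4me1, 49.9% for H3K4me3, 41.8% for Pol2 and 5.88% for CTCF. The comparison asked how far receptor occupancy coincided with each feature of the chromatin landscape. When the GR peaks were shuffled within their chromosomes, the mean overlap was 1.41% for H3K27ac, 8.68% for H3K4me1, 1.10% for H3K4me3, 0.463% for Pol2 and 0.137% for CTCF. The observed overlap was thus 49.1-fold, 7.56-fold, 48.5-fold, 111-fold and 51.7-fold above the shuffled mean, in that order. Shuffled places kept off assembly gaps but not off repeats, which make up 36.4% of the genome. Only 1.37% of GR peaks lay mostly in repeats, so the shuffled means can be too low and the folds too high. Each one-sided permutation p, and each adjusted p over the 5 marks, was 0.001, the smallest that 1000 shuffles can give. Against GR peaks moved by only 10 to 50 kb, which stay in the same neighbourhoods, the folds were 13.4 for H3K27ac, 2.46 for H3K4me1, 18.6 for H3K4me3, 26.8 for Pol2 and 18.9 for CTCF. When peaks within 1 kb also counted as shared they were 23.3 for H3K27ac, 22.3 for H3K4me3, 36.5 for Pol2 and 14.1 for CTCF, and the CTCF fold was 96.1 when 50% of the GR peak had to be covered.

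Sorted by histone marks, GR peaks fell mainly into a promoter class and a group of distal classes. The promoter class, with H3K4me3, held 12338 GR peaks (53.2%). The enhancer class, with H3K4me1 and H3K27ac but without H3K4me3, held 4467 (19.3%, exact 95% interval 18.8 to 19.8%). A further 4622 GR peaks (19.9%) had H3K4me1 as their only mark, 188 (0.811%) had H3K27ac as their only mark, and 1573 (6.78%) had none of the 3. Pol2 overlapped 84.1% of the promoter-class GR peaks, 27.1% of those in the enhancer class and 3.35% of those with H3K4me1 only.

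**Figure D1:**
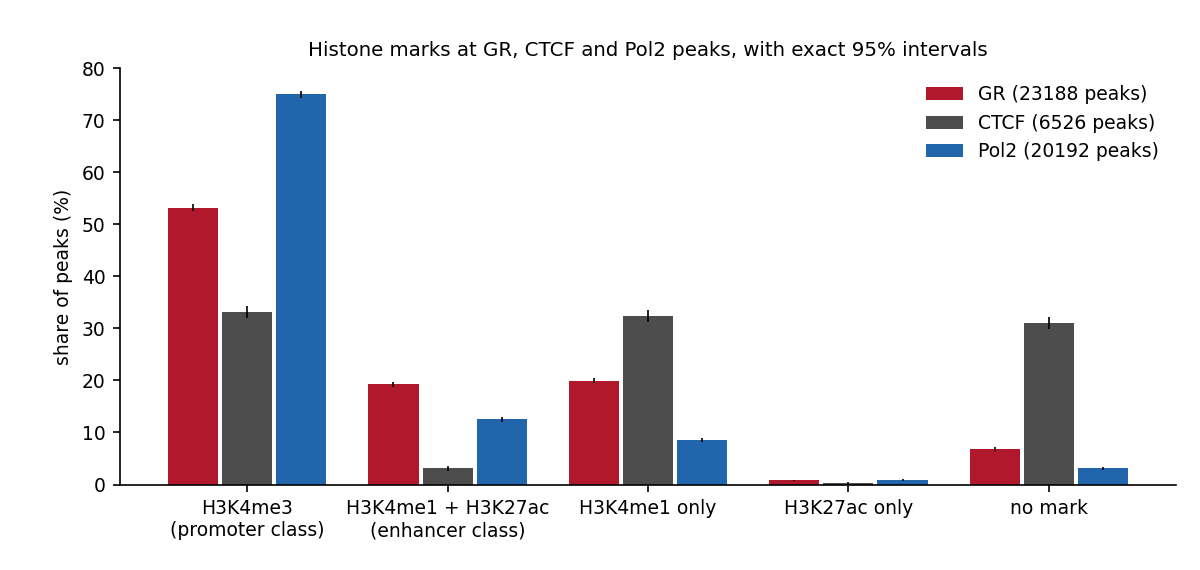
Share of GR, CTCF and Pol2 peaks (vertical axis, percent of the peaks in each list) in each of 5 classes of histone marks (horizontal axis); bars are shares and thin lines are exact 95% intervals, which cover counting error only. GR peaks were in the enhancer class more often (19.3%) than CTCF (3.08%) or Pol2 peaks (12.6%).

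GR sat in enhancer-class chromatin far more often than CTCF, and in promoter-class chromatin less often than Pol2. The enhancer class held 201 of 6526 CTCF peaks (3.08%) against 19.3% of GR peaks, an odds ratio of 7.51 (95% interval 6.50 to 8.72, two-sided Fisher's exact p = 1.15e-288). The promoter class held 2168 CTCF peaks (33.2%), and the odds ratio of GR over CTCF was 2.29 (2.16 to 2.42, two-sided Fisher's exact p = 4.81e-182). CTCF peaks were instead common at sites with H3K4me1 only (32.5%) and at sites with no mark (31.0%). The promoter class held 15145 of 20192 Pol2 peaks (75.0%), giving GR an odds ratio of 0.379 (0.364 to 0.395), with a two-sided Fisher's exact p too small for the software to represent. The enhancer class held 2535 Pol2 peaks (12.6%), giving GR an odds ratio of 1.66 (1.58 to 1.75, two-sided Fisher's exact p = 3.84e-81). Requiring 50% of a peak to be covered ended that last difference (odds ratio 1.03, two-sided Fisher's exact p = 0.285) and raised the enhancer-class odds ratio of GR over CTCF to 15.6. CTCF and H3K4me3 were compared with a different input from the other antibodies, so the antibody and the input cannot be told apart in the comparison of GR with CTCF.

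Distal H3K4me1 regions that held GR carried the acetyl mark and Pol2 much more often than those without GR. Of 60117 H3K4me1 peaks that did not overlap H3K4me3, 5542 overlapped a GR peak. H3K27ac was present at 3245 of these (58.6%) and at 4017 of the 54575 without GR (7.36%), an odds ratio of 17.8 (95% interval 16.7 to 18.9). Pol2 was present at 636 of the H3K4me1 regions with GR (11.5%) and at 395 of those without (0.724%), an odds ratio of 17.8 (15.6 to 20.3). Both two-sided Fisher's exact p values were too small to represent. The H3K4me1 regions with GR were also wider, with a median of 3236 bases against 1123. Within deciles of width the odds ratio was 8.60 for H3K27ac (8.01 to 9.23) and 7.22 for Pol2 (6.26 to 8.33).

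Close to genes, GR peaks gathered at transcription start sites (TSS). The midpoint of 10853 GR peaks (46.8%, exact 95% interval 46.2 to 47.4%) lay within 1 kb of a protein-coding TSS, against 2.71% of shuffled peaks. That is a 17.3-fold excess with a one-sided permutation p of 0.001, the smallest that the shuffles can give. These shuffles did not keep off repeats either. Farther from a TSS, 26.2% of all GR peaks were in introns, 24.0% were intergenic and 2.97% were in exons. H3K4me3 and Pol2 peaks were nearer to genes, with 69.6% and 65.4% within 1 kb of a TSS, and CTCF peaks were farther, with 20.4%. The GR excess was 5.05-fold with a window of 5 kb and 8.12-fold when the TSS of all annotated genes were used.

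Enhancer-class GR peaks were slightly narrower than promoter-class GR peaks, with a median of 222 bases against 246, an enhancer minus promoter difference of -24 bases (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The direction turned when the place of a peak in the deposited list was used instead, a measure chosen after seeing the data. The median place was then 10729 in the enhancer class and 10957 in the promoter class, a difference of -228 places toward the top of the list (two-sided permutation p = 0.26). What the order of the list stands for is not given in the sources used here.

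Some of the 10 widest GR peaks lay at muscle genes, and whether the widest peaks favoured such genes was not tested. The widest, 4129 bases on chromosome 2 from 180399565 to 180403693, overlapped Mir1a-1hg, the host gene of the muscle microRNAs miR-1a-1 and miR-133a-2. It had Pol2 but none of the 3 histone marks, and the nearest protein-coding TSS was that of Slco4a1 at 54617 bases. Another of the 10 widest, 1530 bases from 180385058 to 180386587, lay at the other end of Mir1a-1hg with Gata5 as the nearest protein-coding gene at 51123 bases. A peak of 3191 bases on chromosome 11, from 98383749 to 98386939, covered Tcap, which encodes the sarcomere protein titin-cap, and reached Pnmt, whose TSS was nearest to its midpoint. A peak of 1677 bases on chromosome 7 lay at the promoter of Atp2a1, the calcium pump of fast fibres. Peaks of 2295 and 1899 bases on chromosome 17 lay in Plin4, which encodes a lipid-droplet protein, in the enhancer class. A peak of 2944 bases on chromosome 19, from 23133804 to 23136747, lay 5951 bases from the TSS of Klf9, a glucocorticoid-induced transcription factor gene. A peak of 3106 bases on chromosome 7 lay in the non-coding gene Nctc1, with the nearest protein-coding TSS at Mrpl23, and a peak of 1603 bases on chromosome 10 lay at the promoter of Rev3l. The remaining one, 3900 bases on chromosome 17 from 39843008 to 39846907, overlapped Rn18s-rs5, a pseudogene related to 18S ribosomal RNA, with Esp38 as the nearest protein-coding gene at 105563 bases.

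Several textbook glucocorticoid-induced genes had many GR peaks, but the number varied widely among the GR targets. It ran from 1 at Anxa1 and 2 at Rgs2 to 19 at Dusp1 and 26 at Fkbp5. High numbers were not particular to GR targets, with 11 at the housekeeping gene Actb and 29 at Atp2a1. Fkbp5, a co-chaperone of steroid receptors whose gene lies on chromosome 17 from 28399094 to 28517527, had 26 GR peaks within 25 kb of a TSS. Its widest GR peak, 1139 bases from 28517449 to 28518587, overlapped H3K4me3, H3K27ac, H3K4me1 and Pol2 peaks. The next GR peak began at 28518651. Numbers of GR peaks count each called peak, and neighbours this close need not be separate binding sites. Per1, a clock gene, had 12 GR peaks, Pdk4, a kinase that restrains pyruvate oxidation, had 10, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper GILZ, had 9. Ddit4, an inhibitor of mTOR signalling, had 9 GR peaks, Klf15 had 8 and Glul, which encodes glutamine synthetase, had 6. All 7 of these genes had Pol2, H3K4me3 and H3K27ac within 1 kb of a TSS, and their nearest GR peak lay between 11 bases (Per1) and 344 bases (Ddit4) away. Cebpd, with a GR peak of 1393 bases, Ddit4, with 1346 bases, and Klf9 had the widest peaks among the GR targets.

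**Figure D2:**
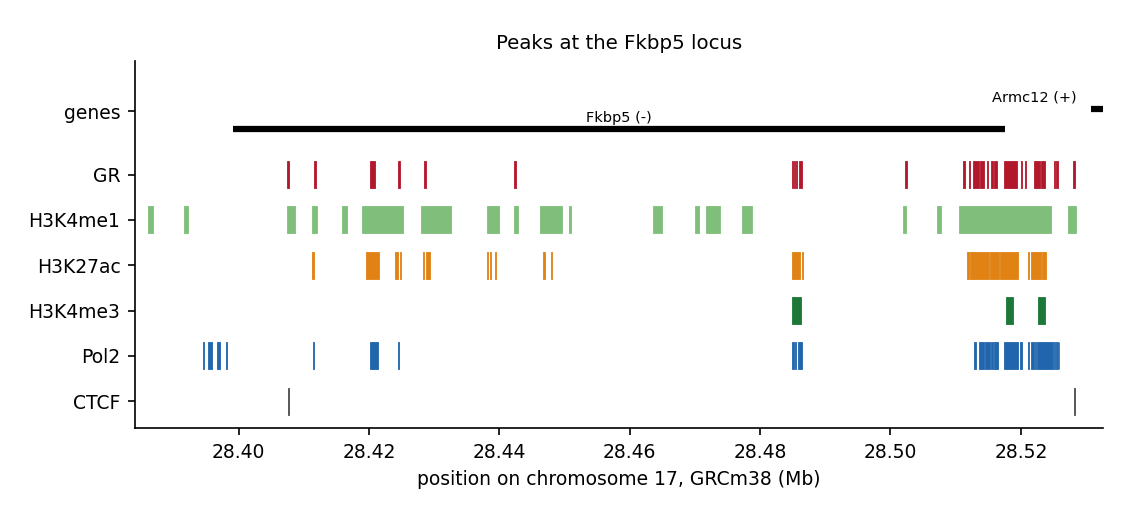
Peaks of each list (coloured blocks, drawn to scale) around Fkbp5 on chromosome 17 of GRCm38 (horizontal axis, Mb), with protein-coding genes as black bars and their strand in brackets. The plotted region from 28384094 to 28532527 holds 28 GR peaks, most of them near the promoter at the right end of Fkbp5, beside 27 Pol2 and 22 H3K27ac peaks.

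Genes of muscle wasting and of insulin signalling carried GR as well. Trim63, which encodes the ubiquitin ligase MuRF1, had 15 GR peaks within 25 kb, and Fbxo32, which encodes the ligase atrogin-1, had 4. Foxo3, a transcription factor that drives both ligases, had 5 GR peaks. Pik3r1, a regulatory subunit of PI3-kinase, had 7 GR peaks. In the same list Sesn1 had the widest peak, 863 bases, followed by Igf1r with 779 and Eif4ebp1 with 668. Mstn, which encodes the muscle growth inhibitor myostatin, had a single GR peak in the enhancer class at 23914 bases. Igf1 had a single GR peak of 123 bases at 270 bases from a TSS, with H3K4me3 and H3K27ac but no Pol2. Nr3c1, the gene of GR itself, had 4 GR peaks, the nearest 3 bases from a TSS, and the muscle regulator Myod1 had 3. Chrna1, a subunit of the acetylcholine receptor, had 1 GR peak at 4439 bases and no Pol2, H3K4me3 or H3K27ac at its TSS. Alb, the liver gene of albumin, had no GR peak within 25 kb, and the nearest was at 94432 bases. Snap25, a neuronal gene, had no Pol2, H3K4me3 or H3K27ac at its TSS and 1 GR peak in an intron, which overlapped none of the 3 histone marks.

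Across the 19 gene lists, GR was near more members than other genes in 9 lists and near fewer members in 1. Of all 21853 protein-coding genes, 58.4% had a GR peak within 25 kb of a TSS. All 25 GR targets had one (Fisher's exact adjusted p = 1.53e-05), as did all 21 genes of muscle atrophy and proteolysis (exact adjusted p = 7.93e-05). So did all 26 genes of fatty acid oxidation and mitochondria, such as Acadm, Acsl1 and Ucp3 (exact adjusted p = 1.53e-05), and all 21 of glucose and glycogen, such as Txnip with 21 GR peaks, Gapdh and Ppp1r3c (exact adjusted p = 7.93e-05). All 19 clock genes, among them Tef with 12 GR peaks, Arntl and Nr1d2, had one (exact adjusted p = 0.000217), and so did all 14 housekeeping genes (exact adjusted p = 0.00149). GR was near 22 of 23 insulin and IGF signalling genes (exact adjusted p = 0.000385) and 17 of 18 muscle transcription factors, such as Mef2a, Mef2d and Smyd1 (exact adjusted p = 0.00257). It was near 23 of 24 sarcomere genes of fast or all fibres (exact adjusted p = 0.000248), with 29 GR peaks at Atp2a1, 20 at Tnnt3 and 7 at Tcap. Pol2 peaks covered 100% of Atp2a1 and 99.4% of Tnnt3. Whether the number of GR peaks near a gene follows its Pol2 coverage was not tested. The widest peak near Tnnt3, 1052 bases, had no histone mark. All p values were two-sided and adjusted over the 19 lists.

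GR occupancy did not pass the test in the other muscle lists, and among the remaining lists it passed as lower at liver genes. It was near 9 of 12 slow sarcomere genes (exact adjusted p = 0.426), where the widest peaks were at Tpm3, Tnni1 and Myh7b. It was near 12 of 14 genes of the neuromuscular junction (exact adjusted p = 0.0937), where the widest were at Rapsn, Ache and Utrn. Liver genes had GR less often, 3 of 14 (exact adjusted p = 0.0117). The cell-type lists did not pass, with 4 of 12 endothelial genes (exact adjusted p = 0.138), 6 of 14 immune genes (0.358), 4 of 11 neuronal genes (0.298) and 6 of 10 adipocyte genes (exact adjusted p = 1). The same held for 9 of 12 genes of fibro-adipogenic cells and fibroblasts (exact adjusted p = 0.426), 9 of 11 satellite cell genes (0.199) and 7 of 10 Schwann cell genes (0.567). The result changed with the background: among genes with H3K4me3 at a TSS, 81.5% had GR within 25 kb, and 4 lists passed instead of 10. Those were the GR targets and the fatty acid oxidation genes, which were higher (exact adjusted p = 0.0433 for each), and the endothelial genes (4 of 11, exact adjusted p = 0.0228) and adipocyte genes (0 of 3, exact adjusted p = 0.0433), which were lower. A window of 100 kb ended the calls for the liver genes (78.6% of members), the muscle transcription factors and the housekeeping genes, and the widest 50% of GR peaks ended that for the liver genes. With a window of 5 kb the endothelial, immune, adipocyte and neuronal genes also passed as lower (exact adjusted p = 0.0121, 0.00449, 0.00449 and 0.0195). With the first 50% of the GR list in its deposited order, a setting chosen after seeing the data, the neuromuscular junction genes passed as higher (85.7% of members, exact adjusted p = 0.00418). The same setting ended the calls for the housekeeping genes (exact adjusted p = 0.104) and the liver genes (exact adjusted p = 0.179).

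**Figure D3:**
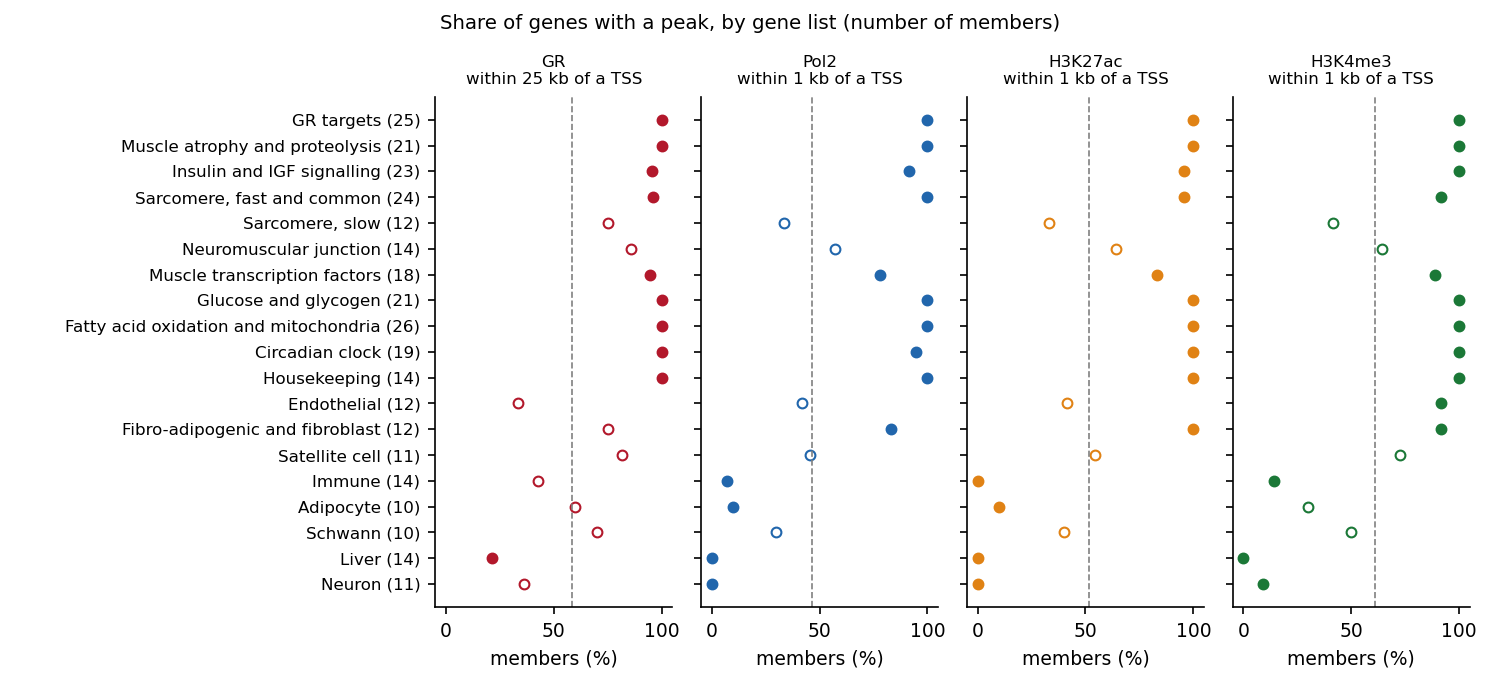
Share of members (horizontal axes, percent) of each of 19 gene lists with a GR peak within 25 kb of a TSS, or a Pol2, H3K27ac or H3K4me3 peak within 1 kb; filled points have an adjusted Fisher's exact p under 0.05 against all other protein-coding genes, open points do not, and dashed lines are the share of all protein-coding genes. Liver and neuron genes lie far to the left in the Pol2, H3K27ac and H3K4me3 panels.

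Pol2 was present at all or most genes of fast muscle and metabolism, and at few or none of the immune, adipocyte, liver and neuronal genes. Pol2 was within 1 kb of a TSS at 46.6% of protein-coding genes. It was present at all 25 GR targets (exact adjusted p = 4.68e-08), all 24 fast or common sarcomere genes (6.71e-08), all 26 fatty acid oxidation genes (4.35e-08), all 21 glucose genes and all 21 atrophy genes (4e-07 for each, all exact). Pol2 was also at 21 of 23 insulin signalling genes (exact adjusted p = 2.79e-05), 18 of 19 clock genes (4.84e-05), all 14 housekeeping genes (5.31e-05) and 14 of 18 muscle transcription factors (0.0139). Slow sarcomere genes had Pol2 at 4 of 12 (exact adjusted p = 0.476) and neuromuscular junction genes at 8 of 14 (exact adjusted p = 0.49). Pol2 was absent from all 14 liver genes (exact adjusted p = 0.000373) and all 11 neuronal genes (exact adjusted p = 0.00235), and was at 1 of 14 immune genes (0.00419) and 1 of 10 adipocyte genes (0.0331). In all, 10 lists were higher and 4 lower for Pol2, 10 and 4 for H3K27ac, and 11 and 3 for H3K4me3. With the strongest 50% of H3K4me3 peaks, 7 lists were higher and 6 lower, and the calls for the fast or common sarcomere genes (37.5% of members, exact adjusted p = 0.627) and the muscle transcription factors (61.1%, exact adjusted p = 0.311) ended. Liver genes had neither histone mark at any of 14 TSS, neuronal genes had H3K4me3 at 1 of 11 and H3K27ac at none, and slow sarcomere genes had H3K4me3 at 5 of 12 and H3K27ac at 4 of 12. No test compared one list with another.

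Markers of resident cells other than muscle fibres were mixed. Genes of fibro-adipogenic cells and fibroblasts had H3K27ac at 12 of 12 (exact adjusted p = 0.00084), H3K4me3 at 11 of 12 (exact adjusted p = 0.0482) and Pol2 at 10 of 12 (exact adjusted p = 0.0245). Endothelial genes had H3K4me3 at 11 of 12 (exact adjusted p = 0.0482), but Pol2 and H3K27ac at 5 of 12 each (exact adjusted p = 0.824 and 0.601). Satellite cell genes had H3K4me3 at 8 of 11 (exact adjusted p = 0.575), H3K27ac at 6 of 11 (exact adjusted p = 1) and Pol2 at 5 of 11 (exact adjusted p = 1). Schwann cell genes had H3K4me3 at 5 of 10, H3K27ac at 4 of 10 and Pol2 at 3 of 10, with exact adjusted p values of 0.575, 0.599 and 0.45. Immune genes had H3K4me3 at 2 of 14 and H3K27ac at none, both lower than other genes (exact adjusted p = 0.00112 and 7.62e-05). With the strongest 50% of H3K4me3 peaks, none of the 12 endothelial genes and none of the 12 fibroblast genes had the mark, so both calls turned to lower (exact adjusted p = 0.0015 for each). The endothelial H3K4me3 call also ended with a window of 5 kb (exact adjusted p = 0.0911). The widest 50% of peaks ended the Pol2 and H3K27ac calls for the fibroblast genes and the Pol2 call for the adipocyte genes (0% of members, exact adjusted p = 0.0509), and with them endothelial genes passed as lower for Pol2 (0%, exact adjusted p = 0.0341). The strongest 50% of H3K4me3 peaks gave a lower call for the adipocyte genes (10% of members, exact adjusted p = 0.0374), and a window of 5 kb ended their H3K27ac call (exact adjusted p = 0.0694).

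The full GR response element (GRE), the palindrome that a GR dimer binds, was far more frequent at GR peaks than in flanking DNA, and more frequent in the enhancer class than in the promoter class. It occurred in 878 of 23168 GR windows of 200 bases (3.79%) and in 0.136% of 44822 flanking control windows, an odds ratio of 28.9 (95% interval 22.3 to 38.1), with a two-sided Fisher's exact p too small to represent. Only 58 of 12323 promoter-class GR peaks held a GRE (0.471%), against 228 of 4466 in the enhancer class (5.11%). Only matches without a mismatch to the GRE consensus were counted, so GREs that depart from it are missing from these shares. The share was 7.77% at GR peaks with H3K4me1 only and 13.9% at the 1570 scanned peaks with no mark. The odds ratio of the enhancer over the promoter class was 11.4 (8.47 to 15.5, two-sided Fisher's exact adjusted p = 3.25e-79), and 4.01 (2.88 to 5.58) within deciles of GC content. The GRE odds ratio against controls was 54.7 in windows of 100 bases, 17.2 in windows of 400 bases and 43.4 against control windows matched for GC content. It was 48.4 for the first 50% of the GR list in its deposited order, a setting chosen after seeing the data.

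The E-box of MYOD, the myogenic factor, occurred in 18.2% of GR peaks and 9.76% of controls, an odds ratio of 2.06 (Fisher's exact adjusted p = 1.85e-207). It was found in 27.2% of enhancer-class and 12.4% of promoter-class GR peaks. Sites for MEF2, another muscle factor, followed the same division, with 6.05% against 1.25% (odds ratio 5.08, exact adjusted p = 1.2e-58), as did AP-1 sites, with 9.43% against 2.48% (odds ratio 4.09, exact adjusted p = 1.35e-73). Promoter-class GR peaks instead held SP/KLF sites (18.7% against 1.43% in the enhancer class) and NRF1 sites (10.6% against 0.313%). Unlike that of the GRE, these comparisons between classes were not made within strata of GC content. How far base composition accounts for them was therefore not tested. Over all GR peaks, SP/KLF sites had an odds ratio of 18.1 against controls and NRF1 sites 25.6, with exact p values too small to represent. CTCF (2.56), NF1 (1.84), STAT (1.78) and AP-1 (1.59) sites were also more frequent in GR peaks than in controls. MEF2 (0.843), CEBP (0.751), FOX (0.620) and ERR (0.362) sites were less frequent, and TEAD sites did not pass (odds ratio 1.05, exact adjusted p = 0.273).

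**Figure D4:**
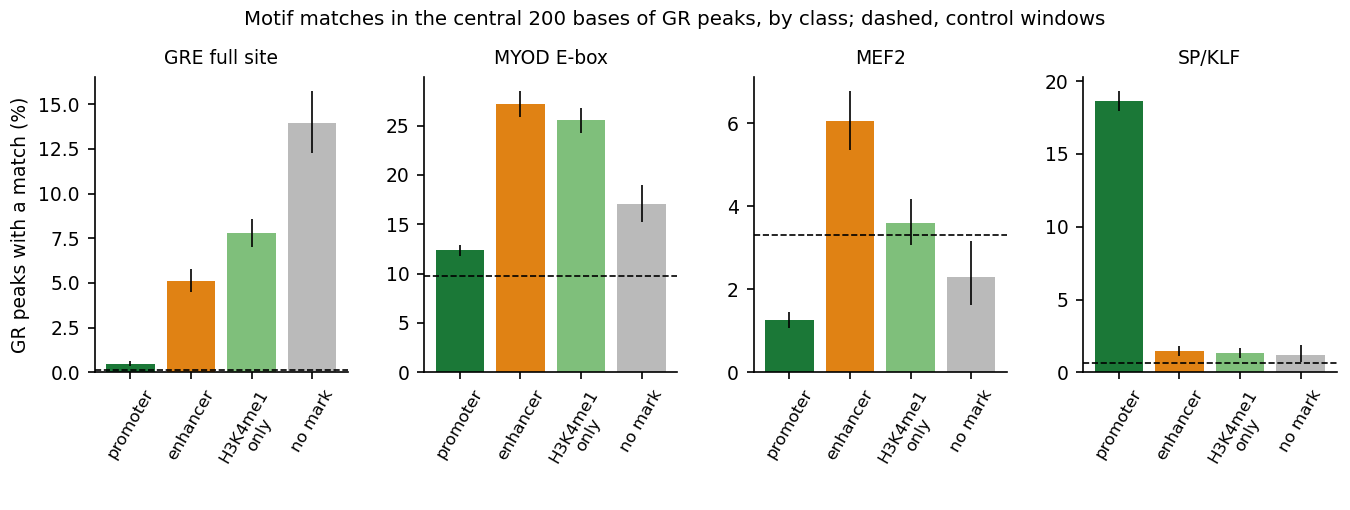
Share of GR peaks (vertical axes, percent) with a GRE, a MYOD E-box, a MEF2 site or an SP/KLF site in their central 200 bases, by class of histone marks (horizontal axes); dashed lines are the share of flanking control windows and thin lines are exact 95% intervals, which cover counting error only. The class of 188 GR peaks with H3K27ac only is not drawn, and GRE shares run from 0.471% in the promoter class to 13.9% in the class with no mark.

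GC content differed between these windows, with a mean of 59.3% in GR peaks, 65.6% in their promoter class, 53.2% in their enhancer class and 45.6% in controls. Against control windows of matched GC content, MEF2 (odds ratio 4.45) and FOX sites (1.82) were more frequent in GR peaks instead of less. In the same comparison TEAD sites also passed (odds ratio 1.33, exact adjusted p = 4.69e-07), CEBP sites turned to 1.17 without passing (exact adjusted p = 0.0845) and ERR sites no longer passed (0.753, exact adjusted p = 0.12). These p values count control windows drawn repeatedly as independent, so they can be too small. The odds ratio of the MYOD E-box fell to 1.20, that of SP/KLF to 2.30 and that of NRF1 to 6.50. In windows of 100 bases the MEF2 call was lost (odds ratio 0.876, exact adjusted p = 0.0591) and TEAD sites passed (odds ratio 1.16, exact adjusted p = 0.0238). As a check of the scan, CTCF peaks held a CTCF motif at 62.3% of 6509 scanned summits against 2.85% of controls. That scan allowed 1 mismatch and used summits, so it does not measure how many GREs were missed at GR peak midpoints.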

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

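The tests on sites shared by CTCF and H3K4me3 were chosen only after the result was seen; the predictions for the other tests in this part were written before those tests were run, although the classes of GR peaks had been looked at earlier.

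Peaks on the mitochondrial genome, which the comparisons leave out, were more than 3 in number in 3 lists. There were 8 such GR peaks, covering 10790 bases, 7 such H3K4me3 peaks, covering 4781 bases, and 5 such CTCF peaks, covering 11471 bases. The deposited fold over the control ran from 3.72 to 5.80 at the CTCF peaks and from 1.63 to 2.66 at the H3K4me3 peaks, and no such value is given for GR in the sources used here.

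GR peaks in promoters rarely held a full GRE, with 0.471% against 5.11% in the enhancer class. The odds ratio of the enhancer over the promoter class was 11.4 overall and 4.01 (95% interval 2.88 to 5.58) within deciles of GC, which argues against GC as the whole cause. Whether GC is part of the cause cannot be told from the smaller value. Mean GC content itself separates the classes, with 65.6% in the promoter class and 53.2% in the enhancer class. A candidate explanation that stays open is that promoter peaks reflect open promoter chromatin rather than receptor at its own site. Promoter-class peaks held a GRE more often than GC-matched controls (odds ratio 29.1, 7.71 to 246), which met the bound set beforehand against this explanation. That bound was wrong, because the excess rests on 58 of 12312 peaks and leaves open what lies behind the other promoter peaks. Only 2 of the controls held a GRE, and the interval counts controls drawn repeatedly as independent. No biological explanation was tested, since the design has a single condition.

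At 468 sites a CTCF peak and an H3K4me3 peak had both edges within 50 bases of each other, which is 7.17% of CTCF peaks. Binding of CTCF at its own motif is argued against, since 0.864% of the 463 scanned sites held the motif (0.236 to 2.20%) against 67.0% of other CTCF peaks. Reads from repeats may account for these sites: 97.0% lay mostly in repeats, 31.7 times the share among other CTCF peaks (26.9 to 37.2). The median fold of the shared sites was higher, 12.9 against 7.28, and leaving them out moved none of the overlap and class comparisons of GR across its threshold. No biological explanation was tested.

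GR peaks with none of the 3 histone marks held a full GRE more often (13.9%) than GR peaks with H3K4me1 only (7.77%). Mean GC content was 48.7% in the unmarked class and 52.2% in the H3K4me1-only class, and this comparison was not made within strata of GC. Marks lying just beside the peak are argued against as the cause, since the 1025 unmarked peaks with no mark within 1 kb kept a higher share (15.8%, odds ratio 2.23, 1.81 to 2.73). The 545 unmarked peaks with a mark within 1 kb had a smaller excess (10.5%, odds ratio 1.39, 1.01 to 1.87). Reads from repeats are argued against by how few peaks lay mostly in repeats, 2.99% of the unmarked and 2.7% of the H3K4me1-only GR peaks. Outside repeats the shares were 13.7% and 7.81% (odds ratio 1.88, 1.56 to 2.26). That comparison left out too few peaks to have come out otherwise, so it adds nothing. Whether weak marks fell below the peak-calling threshold stays open, as the depth is unknown. No biological explanation was tested.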

How the results depend on the processing

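The alternatives based on the order of the GR list, and those without sites shared by CTCF and H3K4me3, were chosen only after the results were seen; all others were planned. Of 88 alternatives to the main results and counts, 85 kept the direction and the side of the threshold or, for counts, stayed within 1.5 times. In the 3 exceptions, 50% coverage brought the odds ratio of GR over Pol2 in the enhancer class to 1.03, the place in the list put the enhancer class nearer the top (a difference of -228 places) although its peaks were narrower (-24 bases), and with genes carrying H3K4me3 as the background 4 gene lists passed instead of 10. The cause was not tested, except that the last background holds fewer genes, most of them with GR nearby. Some counts of lists stayed within 1.5 times only as a sum: with the strongest 50% of H3K4me3 peaks, 11 higher and 3 lower became 7 and 6, and for GR at 5 kb, 9 higher and 1 lower became 9 and 5.

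Among single gene lists for GR, 64 of 94 alternatives gave the same call, 12 ended a call, 5 gained one and 13 turned the direction. In percent of members with GR, the turned values were 41.7 (slow sarcomere), 27.3 (satellite cell), 0 (adipocyte) and 30 (Schwann) at 5 kb; 91.7 (endothelial), 78.6 (immune) and 78.6 (liver) at 100 kb; 0 (adipocyte) and 100 (neuron, 1 gene) among genes with H3K4me3; 41.7 (fibroblast) and 40 (Schwann) with the widest 50% of GR peaks; and 33.3 (fibroblast) and 40 (adipocyte) with the first 50% of the list. Liver genes had no member with H3K4me3, so that alternative gave no value for them. For H3K4me3, 29 of 38 alternatives gave the same call, and the strongest 50% of peaks turned 37.5 (fast sarcomere), 35.7 (neuromuscular junction), 0 (endothelial), 0 (fibroblast), 36.4 (satellite cell) and 50 (Schwann). For H3K27ac, 35 of 38 gave the same call, and the satellite cell genes turned to 36.4 with the widest 50% of peaks. For Pol2, 35 of 38 gave the same call and none turned. For motifs, 51 of 65 gave the same call. The turned odds ratios were those of TEAD, 0.945 in windows of 400 bases, 0.979 for the widest 50% and 0.993 for the first 50% of GR peaks, and those against GC-matched controls, 4.45 for MEF2, 1.17 for CEBP and 1.82 for FOX. The cause of these turns was not tested.

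No paired analysis was possible because each antibody has 1 library and every replicate number is 1. With no replicates, leaving out libraries in turn gives no value, and weak sites below the peak-calling threshold are not seen at an unknown depth.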

Other observations

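The tests of peak numbers near gene lists and of E-boxes beside GREs, and the summaries by place in the list, by fold and by gene body in this part, were chosen only after the data were seen.

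Among genes with H3K4me3 at a TSS, the number of GR peaks within 25 kb was higher than in random gene sets for 8 lists and lower for 2; lists were not compared with one another. GR targets and fast sarcomere genes each had a median of 7 GR peaks against 2 in other genes. Each called peak was counted, also where peaks lay close together. Set against 100000 random gene sets of like TSS span, the mean of log2(number + 1) was higher by 1.74 for the fast sarcomere list, 1.46 for GR targets, 1.30 for glucose and glycogen and 1.04 for the clock (two-sided permutation adjusted p = 8e-05 for each; the smaller one-sided p was doubled, so 2e-05 before adjustment is the smallest that these sets can give). It was higher by 0.73 for muscle atrophy (permutation adjusted p = 0.000512), 0.66 for muscle transcription factors (0.0074), 0.62 for fatty acid oxidation (0.00101) and 0.49 for insulin signalling (0.014). It was lower at endothelial genes, with a median of 0 and a difference of -0.91 (permutation adjusted p = 0.00119), and at the 3 adipocyte genes, with -1.33 (permutation adjusted p = 0.024). The slow sarcomere, neuromuscular junction, housekeeping, fibroblast, satellite cell and Schwann lists did not pass, with permutation adjusted p values of 0.213, 0.352, 0.132, 0.83, 0.32 and 0.234.

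Pol2 covered long stretches of some genes, picked here after their values were seen. It covered 168340 bases of Ttn (60.4% of the gene), 58166 bases of Mylk4 (70.0%) and 61988 bases of Zbtb16 (34.1%), a glucocorticoid-induced gene. The whole of Myh4, the gene of a fast myosin heavy chain, and the whole of Atp2a1 were covered (100%), as were 99.4% of Tnnt3 and of Pvalb. Pol2 also covered 97.8% of Pdk4, 92.7% of Trim63, 87.0% of Ucp3, 80.9% of Pygm and 57.6% of Fbxo32, which stood far above the medians of their lists: 1.82% for muscle atrophy, 1.86% for fatty acid oxidation, 13.5% for glucose and glycogen and 9.51% for GR targets. The median covered share was 67.4% in the fast sarcomere list and 0 in the slow list, where 4 of 12 genes had any Pol2. The higher numbers of GR peaks in the fast sarcomere list were not tested against this coverage.

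Several of the first entries of the GR list lay at known glucocorticoid-induced genes. The first was the promoter peak of Fkbp5, the second lay outside genes at 87596 bases from the TSS of Ptpn1, the third in an intron of Klf13, the fourth in an intron of Fkbp5, the fifth in an intron of Hif3a, the sixth in an intron of Zbtb16, the seventh in Per1 and the eighth 22714 bases from the TSS of Ddit4. Other entries had their nearest protein-coding TSS at Usp24 (116107 bases, place 10), Cdkn2aipnl (51533 bases, place 13) and Syk (139594 bases, place 14). A full GRE was found in 18.4% of the first decile of the list, 4.79% of the next and 1.12% of the last. By width the share was 1.86% in the widest decile, 4.92% in the fifth and 2.85% in the narrowest. The GRE share was thus lowest in the widest decile, which limits width as a stand-in for strength. Across peaks, which are not independent replicates, place in the list and width had a Spearman correlation of -0.551 for GR and -0.773 for H3K27ac. In the first decile of the GR list, 34.6% of peaks were in the enhancer class and 37.9% in the promoter class.

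Of 9087 GR peaks in the enhancer and H3K4me1-only classes, 587 held a full GRE. The MYOD E-box occurred in 19.1% of those and in 26.9% of the others, an odds ratio of 0.642 (0.515 to 0.795, two-sided Fisher's exact p = 2.4e-05).

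CTCF peaks with the highest fold held the CTCF motif less often than those with the lowest, 37.1% in the top decile against 71.0% in the bottom decile. In the top decile 84.5% overlapped H3K4me3 and 34.8% were sites shared with an H3K4me3 peak. Without the shared sites 56.1% of the top decile held the motif.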
